A study of Homo sapiens and Rattus norvegicus with 14 samples.

How the data were processed

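The series measured open chromatin by ATAC-seq in nuclei of 2 segments of the kidney tubule, the proximal tubule (PT) and the medullary thick ascending limb (mTAL). Per the labels' protocols, small pieces of human and rat kidney were digested with collagenase in several rounds, the segments were isolated, and their nuclei were exposed to a transposase that inserts sequencing adapters into accessible DNA. The rats were of a salt-sensitive inbred strain. There were 14 libraries, with 3 of mTAL and 4 of PT in each species. The labels number the replicates but do not say whether they came from separate donors or animals, so p-values measure only the spread between these libraries, which may be technical.

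For each library the authors deposited 1 list of peaks, called per library and not on pooled replicates. The deposited lists have no header. From their layout, the deposited score column holds a whole number per peak, the deposited fold column a ratio of signal to background, and 2 deposited columns the −log10 of a p-value and of a q-value. A further deposited column, of the kind other than these, gives the offset of the peak summit within its interval. The submitters' processing notes name Bowtie2, MACS2 and HOMER and the genome builds hg38 and rn7, without saying what each was used for. Marks in the deposited names are read here as removal of duplicate and mitochondrial reads and a p threshold of 0.01, which the processing notes do not describe. Other marks in these names are not explained and were not used, and whether the lists were limited in length is not known. The peak caller's other settings and read depth per library are not given in the sources used here. The scores, folds and −log10 values are the authors' own and were used only to describe, rank or filter peaks within a list. The lowest deposited −log10 p lay between 2.00 and 2.98, so the lists do not end at the same level. The deposited lists held 200406 to 296980 rows, including several rows for intervals with more than 1 summit. Because read depth is unknown, no counting interval can be given for a single peak.

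Overlapping rows of a library were merged, chromosome Y and the mitochondrial genome were left out, and merged peaks were ranked by their best −log10 p. The 50000 best per library were kept, so that each library contributed the same number. Peaks of the 7 libraries of a species that overlapped by at least 1 bp were merged into regions. A region was called segment-only when it was present in all libraries of 1 segment and in none of the other. Presence or absence of a single region was not tested, since an exact test over 35 splits cannot pass an adjustment over this many regions. The number of segment-only regions was instead set against the 35 splits. Similarity of 2 libraries was the Jaccard index in base pairs of their kept peaks, and the mean within segments minus the mean between segments was tested with an exact one-sided permutation test. The smallest p this test can give is 0.0286. An exact test over both species used the 1225 pairs of splits.

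Human genes came from a RefSeq gene table of assembly GRCh38.p14, which shares the chromosome coordinates of hg38. Of its 59792 rows, 789 that carry positions on scaffolds outside the chromosomes were left out, a choice made after a first run had shown them, and 19821 protein-coding genes were used. For each gene and library, the regions overlapping the gene body and 10 kb on either side were counted. The value is a number of called regions, not of reads. Genes with a mean of at least 1 region over the 7 human libraries were tested with limma 3.58.1 (trend) in R 4.3.3 on log2(number of regions + 1), as PT minus mTAL, with the Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with few regions. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 27 lists, and again with an estimated correlation. Of the 421 genes of the lists, 420 were found in the table. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest. Confidence intervals of shares are 95% Wilson intervals and cover counting error only.

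The gene test was tested on simulated data, with Poisson counts at the means of the real genes and 200 changed genes with means of 5 to 30 regions, in 5 draws. It recovered 12.4% of genes changed 2-fold and 82.0% of those changed 4-fold, and called on average 0 genes in draws without change. The simulated counts lack the many genes of the real data whose count is identical in all libraries of a group. They also hold no spread between libraries beyond that of Poisson counts. The median tested gene of the real data had 2.14 regions, below the range of the changed genes. The recovery and the lack of false calls therefore do not carry over to most real genes.

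The groups, the tests of the comparisons, the gene lists and the main alternatives were fixed before the data were examined, except those said to be chosen later. The tests of the 4 measures of the libraries were not in that plan. The genes named by rule are all members of the PT core and mTAL core lists, the 5 genes with the smallest p in each direction among those past the threshold (ties by larger absolute fold change, then by symbol), up to 4 members past the threshold with the largest absolute fold change from each other list, and the 2 segment-only regions per segment whose worst rank within the segment was best. The parts of the rule for rat genes, motifs and the comparison of species could not be applied, and genes next to a named region are given as its position. A member of each core list is not reported here by itself and stays in the tests of its lists. Other genes named outside this rule are said to be chosen after their values were seen. The 27 lists covered proximal tubule transport and metabolism, thick ascending limb transport, transcription factors of both segments, blood pressure genes and markers of other kidney cell types. Alternatives changed the number of peaks kept, the overlap that counts as presence, the pseudocount, the filter on genes with few regions, the gene window, the measure per gene and the libraries used.

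Several planned analyses were not run. No rat annotation, no genome sequence and no gene strand were used here, so gene tests, gene lists and locations in the rat, the comparison of gene effects between species, and shares of peaks with transcription factor motifs were left out. Windows around gene starts were replaced, after the files had been seen, by windows around both ends of a gene. Transcriptome data of these segments were not analysed here.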

Results

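Open chromatin was mapped by ATAC-seq in proximal tubule (PT), the segment that reclaims most of the filtered load, and in medullary thick ascending limb (mTAL), the segment that reabsorbs sodium chloride in the renal medulla. Human kidney and kidney of a salt-sensitive rat strain each gave 3 mTAL and 4 PT libraries. The title of the series sets the maps in the context of noncoding variants linked to blood pressure, and the design compares the 2 segments within each species. After overlapping rows were merged, the lists held 190996 ± 17534 peaks in human mTAL (SD, n = 3), 223732 ± 19608 in human PT (n = 4), 248160 ± 9431 in rat mTAL (n = 3) and 256021 ± 32164 in rat PT (n = 4). Peaks with a deposited q of at most 0.01 numbered 126612 ± 30941 in human mTAL, 119528 ± 20823 in human PT, 137083 ± 49417 in rat mTAL and 65299 ± 17319 in rat PT.

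Over both species together the strongest peaks of mTAL covered more of the genome than those of PT. The 50000 best peaks covered 32.7 ± 5.33 Mb in human mTAL (SD, n = 3) and 22.3 ± 3.06 Mb in human PT (n = 4). In the rat they covered 20.8 ± 6.55 Mb in mTAL and 15.3 ± 1.10 Mb in PT. Most of the rat difference comes from rat mTAL replicate 1 (28.1 Mb), since rat mTAL replicates 2 and 3 covered 18.7 and 15.5 Mb against 13.9 to 16.6 Mb in the rat PT libraries. The test was not repeated without rat mTAL replicate 1. The mean log2 difference over both species, PT minus mTAL, was -0.47 (exact two-sided permutation test over both species, p = 0.00163, adjusted p = 0.00653 over 4 measures of the libraries). The difference did not itself differ detectably between the species (rat minus human 0.16, exact p = 0.698). The enrichment of the libraries moved with the segment in human: the median deposited fold of the kept peaks lay between 7.43 and 11.5 in the mTAL libraries and between 3.58 and 6.60 in the PT libraries. In the rat these medians overlapped, at 3.87 to 5.17 in mTAL and 3.84 to 4.68 in PT. The −log10 p of the last kept peak did not overlap in the rat, with 5.52 to 9.90 in mTAL and 4.65 to 5.23 in PT, and did in human (7.58 to 25.6 and 5.69 to 8.65). Over both species its mean log2 difference was -0.87 (exact permutation test, adjusted p = 0.00653) and that of the median fold -0.52 (adjusted p = 0.0261). The number of merged peaks went the other way without passing the threshold (0.13, exact permutation test, adjusted p = 0.110). The tests of these 4 measures were not among those fixed before the data were examined.

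Human libraries of the same segment shared more of their open chromatin than libraries of different segments. The mean Jaccard index was 0.409 within segments and 0.323 between them, a difference of 0.0863 (exact one-sided permutation test, p = 0.0286, the smallest possible). The next highest of the 35 splits gave 0.0841. Within human mTAL the mean index was 0.504, and within human PT it was 0.362. PT replicate 1 shared little with any library, with indices of 0.281 to 0.296 to the other PT libraries. mTAL replicate 3 had an index of 0.452 to PT replicate 2, against 0.376 and 0.346 for mTAL replicates 1 and 2. With the 100000 best peaks the human difference was 0.0742 (exact p = 0.0571), with all deposited peaks 0.0512 (exact p = 0.114) and with peaks at a q of at most 0.01 it was 0.0645 (exact p = 0.0571). Leaving out 1 library ended the call in each case. The difference was 0.0574 without mTAL replicate 1 (exact p = 0.267), 0.0414 without mTAL replicate 2 (exact p = 0.267) and 0.0794 without mTAL replicate 3 (exact p = 0.0667, the smallest possible). Without PT replicate 1, 2, 3 or 4 it was 0.110, 0.116, 0.101 and 0.112 (exact p = 0.1 each, the smallest possible).

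Rat libraries shared less, at a mean Jaccard index of 0.227 within and 0.195 between segments. The difference of 0.0319 was exceeded by 1 of the other splits (exact one-sided permutation test, p = 0.0571). With peaks at a q of at most 0.01 it was 0.0356 (exact p = 0.0286), and with all deposited peaks 0.0118 (exact p = 0.114). It was 0.00489 without rat mTAL replicate 1 (exact p = 0.4), 0.0126 without rat mTAL replicate 2 (0.333) and 0.0269 without rat mTAL replicate 3 (0.267). Without rat PT replicate 2 it was 0.0479, and without rat PT replicate 4 it was 0.0502 (exact p = 0.1 each, the smallest possible). Within rat mTAL the mean index was 0.287. Within rat PT it was 0.197, close to the 0.195 between segments, so the rat difference came mostly from rat mTAL replicates 1 and 2. This pair had the highest rat index, 0.387, while rat mTAL replicate 3 had 0.211 and 0.264 to them. To the rat PT libraries rat mTAL replicate 3 had 0.1545 to 0.2161, so it did not stand clearly with its own segment. Rat PT replicate 2 reached at most 0.168 with any library. Over both species the mean difference was 0.0591, and 3 of the 1225 pairs of splits gave as large a value (exact one-sided permutation test, p = 0.00245).

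**Figure D1:**
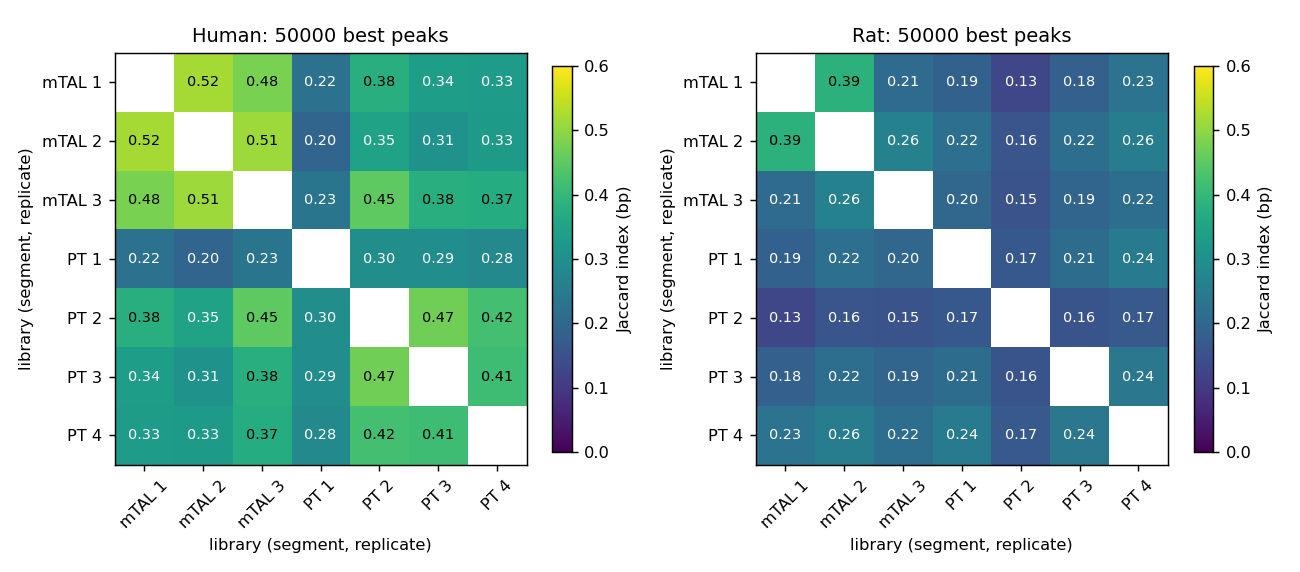
Jaccard index in base pairs between the 50000 best peaks of each pair of libraries, with human libraries on the left and rat libraries on the right and the color scale from 0 to 0.6. The human mTAL libraries form the most similar group (mean 0.504), and human PT replicate 1 has no index above 0.296.

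Human mTAL and PT were separated by 4856 of 124608 regions. Of these, 4184 were present in all 3 mTAL libraries and in no PT library, and 672 in all 4 PT libraries and in no mTAL library. A further 14184 regions were shared by all 7 libraries. The highest count in any other of the 35 splits was 1990. Leaving out any library loosens the rule for a segment-only region, so a rise in these counts is not by itself particular to that library. Leaving out mTAL replicate 1 gave 5151 mTAL-only and 748 PT-only regions, and mTAL replicate 2 gave 5299 and 776. Leaving out mTAL replicate 3 gave 9263 and 1701, and leaving out PT replicate 1 gave 4382 and 1695. PT-only regions numbered 1042 without PT replicate 2 and 1264 without PT replicate 4. With both mTAL replicate 3 and PT replicate 1 left out, a choice made after their values were seen, there were 9599 and 3517. The 25000 best peaks per library gave 1624 and 366, the 100000 best 10615 and 790, and all deposited peaks 14169 and 2038, peaks at a q of at most 0.01 12887 and 636, and presence only where peaks cover at least 50% of a region 6452 and 403.

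The leading mTAL-only region lay on chromosome 7 at 142885320 to 142886109 (hg38). It overlapped TRPV6, an epithelial calcium channel gene, whose neighbour TRPV5 lay 21992 bp away. This region ranked between 2646 and 6979 among the peaks of the 3 mTAL libraries. The next was on chromosome 4 at 117134133 to 117134834, between TRAM1L1 (48557 bp away) and NDST3 (898488 bp away) and outside any gene of the table. The leading PT-only region covered 3585 bp of chromosome 21 at 8227299 to 8230883, where the table lists no gene of any kind. This merged region was much wider than the kept peaks of the human PT libraries, whose median widths were 282 to 405 bp. Whether it holds repeated sequence was not examined. Its nearest protein-coding genes, LOC102723475 and LOC101927345, were 397667 bp and 1129126 bp away. The next PT-only region, on chromosome 19 at 15933774 to 15934148, overlapped CYP4F11, a cytochrome P450 gene in a cluster with CYP4F2 (35700 bp away). Exons and introns were not used here, so the position within TRPV6 or CYP4F11 is not given.

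In rat, 2433 of 203640 regions separated the segments, 1976 of them mTAL-only and 457 PT-only, and 7388 were shared by all 7 libraries. The highest count in any other split was 1060. Without rat mTAL replicate 3 there were 8667 mTAL-only and 551 PT-only regions, and without rat PT replicate 2 there were 2195 and 1294. Without rat mTAL replicate 1 there were 2774 and 619, and without rat mTAL replicate 2 there were 2812 and 524. PT-only regions numbered 718 without rat PT replicate 1 and 823 without rat PT replicate 3. The 25000 best peaks per library gave 1063 and 290, the 100000 best 2910 and 765, and all deposited peaks 4528 and 1481, peaks at a q of at most 0.01 4126 and 352, and 50% coverage 1734 and 251. The leading rat mTAL-only regions lay on chromosome X at 17250699 to 17250914 and on chromosome 20 at 4870515 to 4871051 (rn7). The leading rat PT-only regions lay on chromosome 3 at 61273329 to 61273833 and on chromosome 14 at 65584770 to 65585358. Rat genes were not analysed here.

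**Figure D2:**
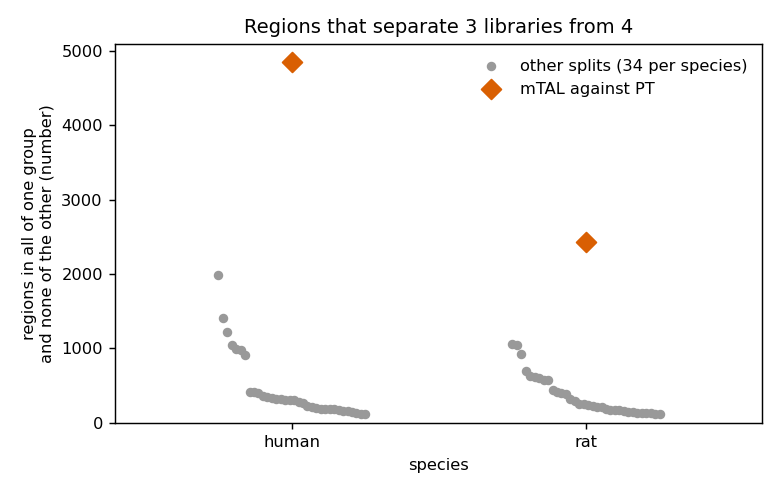
Number of regions present in all libraries of one group and in none of the other, for the 35 ways to split 7 libraries into 3 and 4, in human and rat. The diamond is the split into mTAL and PT (4856 in human, 2433 in rat) and the gray points are the other splits, which reach 1990 and 1060.

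Human regions that separated the segments lay mostly away from gene ends. Of the regions shared by all 7 libraries, 58.4% (95% Wilson interval 57.6 to 59.2) lay within 1 kb of an end of a protein-coding gene. The share was 3.73% (3.20 to 4.35) among mTAL-only regions and 8.48% (6.60 to 10.8) among PT-only regions. Most of the others were split between gene bodies (46.4% of mTAL-only and 44.9% of PT-only regions) and the space between genes (49.9% and 46.6%). Regions found in 1 library alone also had a low share at gene ends, 4.02% (3.86 to 4.18). Per library, 23.9 ± 0.62% of the kept peaks in mTAL (SD, n = 3) and 25.7 ± 2.16% in PT (n = 4) lay at gene ends (exact two-sided permutation test, p = 0.229). This design cannot give a two-sided p below 0.0571.

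The list of genes that mark the thick ascending limb had more open regions in human mTAL. The 12 genes of the mTAL core list held 4.61 ± 0.79 regions per gene in mTAL (SD, n = 3) and 2.29 ± 0.37 in PT (n = 4), and all 12 had a negative log2 fold change (PT minus mTAL), with a median of -0.83. mTAL replicate 3 had 3.83 regions per gene, against 4.58 and 5.42 in mTAL replicates 1 and 2. The list fell in PT relative to other genes (limma camera, adjusted p = 0.000222 at the preset correlation). With the correlation estimated from the data the call was lost (adjusted p = 0.534 with an estimated correlation). Markers of intercalated cells, the distal convoluted tubule and injury also had lower means in PT, without passing the threshold. No member passed the threshold over all genes, and 3 had more regions in mTAL adjusted over the list alone. PTGER3, a prostaglandin E2 receptor gene (gene ID 5733, chromosome 1, 70852358 to 71047816), had 10.3 ± 4.04 regions in mTAL and 3 in every PT library (log2 fold change -1.43, SE 0.26, adjusted p = 0.0974). The chloride channel subunit gene BSND (gene ID 7809, chromosome 1, 54998933 to 55017172) had 5 ± 1 and 1.75 ± 0.96 regions (-1.18, SE 0.30, adjusted p = 0.209). The calcium-sensing receptor gene CASR (gene ID 846, chromosome 3, 122183668 to 122291629) had 7.33 ± 0.58 and 3.25 ± 0.96 regions (adjusted p = 0.117).

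Other mTAL core genes differed by less or varied more. SLC12A1, the sodium-potassium-chloride cotransporter of this segment (gene ID 6557, chromosome 15, 48206302 to 48304078), had 3.33 ± 0.58 regions in mTAL and 1.25 ± 0.96 in PT. The potassium channel gene KCNJ1 had 4.67 ± 1.15 and 2.25 ± 1.71. Among the claudins of the tight junction, CLDN19 had 1.67 ± 0.58 and 0.50 ± 0.58 regions, CLDN16 had 3.67 ± 0.58 and 2.5 ± 1, and CLDN10 had 6.33 ± 0.58 and 4.75 ± 1.89. UMOD, which encodes uromodulin, had 2.33 ± 0.58 and 1.5 ± 1, and EGF had 5 ± 1 and 3.75 ± 1.5. The transcription factor gene IRX1 had 1.33 ± 1.15 and 0.75 ± 0.50. With all deposited peaks CLDN19 was 0.15, near the median of all genes in that setting (0.16), so no difference relative to other genes was left. The direction turned for EGF with the 25000 best peaks (0.53), and for CLDN10 and IRX1 when each region was given to its nearest gene (0.05 and 0.88). In a fit with the replicate number as a block, the log2 fold change shrank from -0.43 to -0.14 for CLDN10 and from -0.38 to -0.18 for EGF.

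The list of genes that mark the proximal tubule had more open regions in human PT at the preset correlation, with exceptions among its genes and among the mTAL libraries. The 12 genes of the PT core list held 2.94 ± 1.35 regions per gene in mTAL (SD, n = 3) and 4.46 ± 0.79 in PT (n = 4), and 9 of the 12 had a positive log2 fold change, with a median of 0.71. In mTAL replicate 3 the list held 4.50 regions per gene, against 2.17 in each of the other mTAL libraries and 3.75 to 5.33 in the PT libraries. The list rose in PT (limma camera, adjusted p = 0.0264 at the preset correlation), and the call was lost with the correlation estimated from the data (adjusted p = 0.605 with an estimated correlation). It was also lost without mTAL replicate 1 (adjusted p = 0.0501), mTAL replicate 2 (0.180), PT replicate 1 (0.0728) or PT replicate 2 (0.134), and was kept without mTAL replicate 3 (0.000226). All deposited peaks (0.0600), a mean of at least 3 regions (0.0635), and windows of gene bodies alone (0.0854) or 5 kb around gene ends (0.0897), both chosen later, also ended the call. No member passed the threshold over all genes or adjusted over the list alone.

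Among the PT core genes, the organic anion transporter gene SLC22A8 (gene ID 9376, chromosome 11, 62992824 to 63015841) had 0.67 ± 1.15 regions in mTAL and 4.75 ± 2.22 in PT (log2 fold change 1.90, SE 0.55, adjusted p = 0.257). The dicarboxylate transporter gene SLC13A3 (gene ID 64849, chromosome 20, 46557828 to 46684485) had 2.33 ± 1.53 and 7 ± 1.41 (1.35, SE 0.34, adjusted p = 0.213). HNF4A, a transcription factor of the proximal tubule (gene ID 3172, chromosome 20, 44355699 to 44434596), had 1, 1 and 6 regions in the 3 mTAL libraries and 7 ± 0.82 in PT (1.39, SE 0.48, adjusted p = 0.346). Without mTAL replicate 3, HNF4A passed the threshold (1.99, adjusted p = 0.00158), as did PTGER3 of the mTAL core list (-1.75, adjusted p = 0.00175). PTGER3 also passed with 50% coverage (adjusted p = 0.0349) and in base pairs covered (0.0466), CASR in base pairs covered (0.0392), and SLC13A3 with all deposited peaks (1.38, adjusted p = 0.0365). With both mTAL replicate 3 and PT replicate 1 left out, a choice made later, SLC34A1 (0.74, adjusted p = 7.1e-05), SLC22A8 (2.71, 0.0175), SLC13A3 (1.82, 0.0390), HNF4A (1.94, 0.00129), PTGER3 (-1.75, 0.00608) and IRX1 (-0.58, 6.9e-06) passed. These 2 libraries were left out after they had stood apart, PT replicate 1 among others at SLC34A1 and IRX1 themselves. The remaining mTAL and PT libraries had 2 and 4 regions each at SLC34A1, and 2 and 1 at IRX1. Such small p-values rest on identical counts within each group, and none of these calls is independent support. SLC22A6 had 0.33 ± 0.58 and 2.25 ± 0.96 regions, SLC5A12 1.33 ± 2.31 and 2.75 ± 1.71, and GATM 2.33 ± 0.58 and 3.50 ± 1.29. All mTAL regions of SLC5A12 (0, 0 and 4), SLC22A6 and SLC22A8 were in mTAL replicate 3. SLC22A6 and SLC22A8 are neighbours whose windows overlap, so a region in the overlap counts for both and these 2 genes are not independent. The log2 fold change of SLC5A12, 1.02 with all libraries, was 1.79 without mTAL replicate 3 and 0.63 without mTAL replicate 1 or 2. The glucose transporter gene SLC5A2 had 2.67 ± 1.53 and 3.25 ± 0.50, and the endocytic receptor gene LRP2 had 2 in every mTAL library and 2.50 ± 1.29 in PT. CUBN (7.33 ± 1.53 and 5.75 ± 2.06), SLC4A4 (9.33 ± 4.04 and 8.25 ± 2.75) and the phosphate transporter gene SLC34A1 (log2 fold change -0.09) did not have more regions in PT on the log2 scale. SLC34A1 had no region in PT replicate 1 and 4 in each other PT library, and its log2 fold change was 0.49 without that library and 0.16 without mTAL replicate 3. SLC4A4 turned to 0.16 without mTAL replicate 3 and 0.05 without PT replicate 4, SLC5A2 to -0.08 without mTAL replicate 2, and LRP2 to -0.06 without PT replicate 2.

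**Figure D3:**
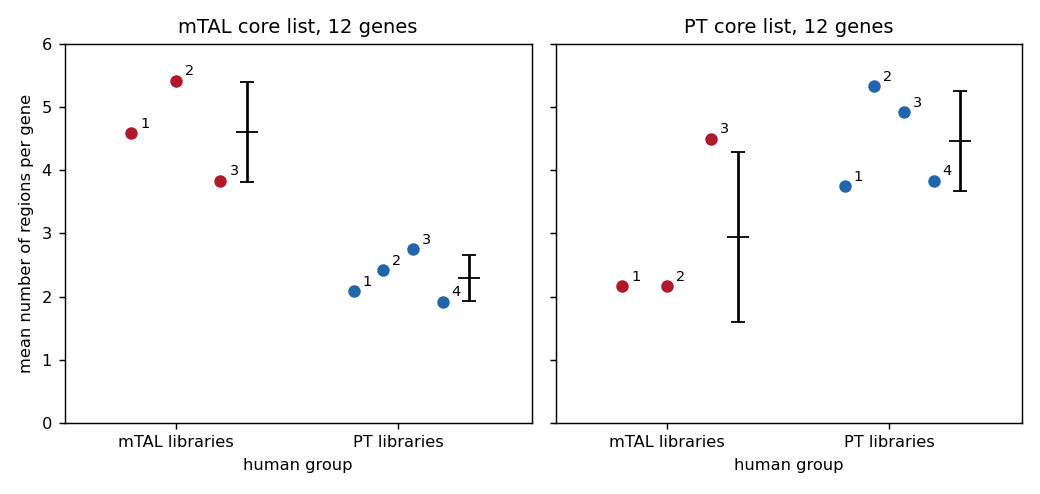
Mean number of open regions per gene in each human library for the mTAL core list (left) and the PT core list (right), 12 genes each. Points are libraries with their replicate numbers and the bars give the mean and SD of each group. In the PT core list, mTAL replicate 3 (4.50) lies among the PT libraries (3.75 to 5.33).

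**Figure D4:**
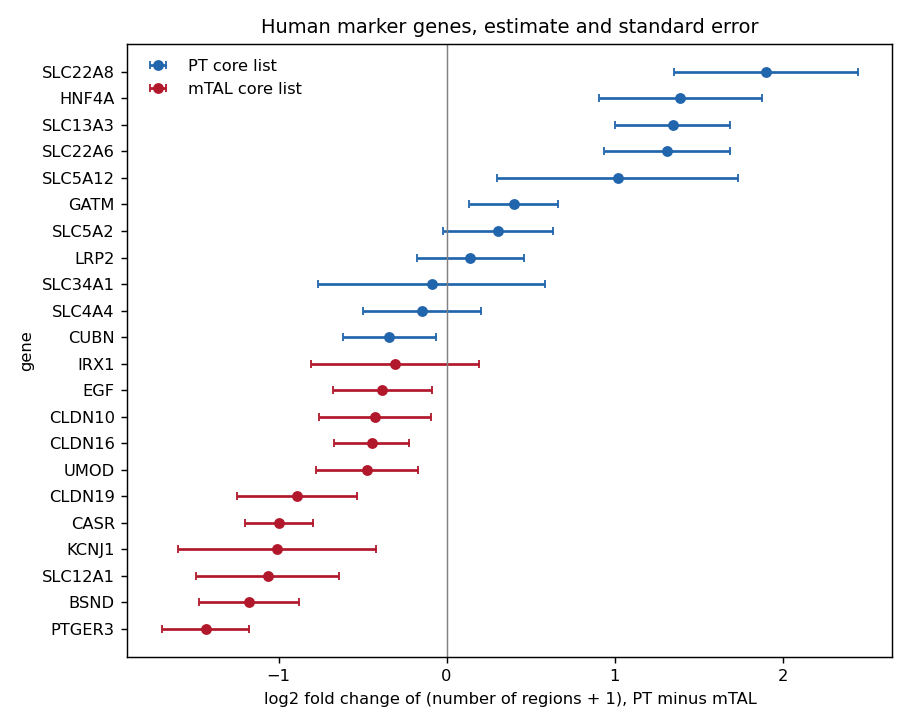
Log2 fold change of the number of regions plus 1, PT minus mTAL, for 22 genes of both core lists, with bars for the standard error from limma (3 mTAL and 4 PT human libraries). The 11 mTAL core genes drawn all lie below 0, and 8 of the 11 PT core genes drawn lie above 0.

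Among the metabolic lists of the proximal tubule, 2 of 3 rose in PT at the preset correlation. The list of amino acid and small molecule metabolism rose in PT (2.53 ± 0.51 regions per gene in mTAL, 3.62 ± 0.66 in PT, camera adjusted p = 0.000233), with a positive log2 fold change in 21 of 27 tested genes. mTAL replicate 3 had 3.11 regions per gene, against 2.30 and 2.19 in mTAL replicates 1 and 2. That call was lost with the correlation estimated (adjusted p = 0.539 with an estimated correlation). It was also lost with all deposited peaks (adjusted p = 0.101), a mean of at least 3 regions (0.137) and 5 kb windows around gene ends (0.0601). The only member past the threshold over all genes was PRODH2, a mitochondrial hydroxyproline dehydrogenase gene (gene ID 58510, chromosome 19, 35799988 to 35812845). It had no region in any mTAL library and 1.75 ± 0.50 in PT (limma adjusted p = 0.0201), and missed the threshold without mTAL replicate 1 (adjusted p = 0.102), 2 (0.0894) or 3 (0.0566). Without PT replicate 2, 3 or 4 its mean was below 1 region and it was not tested. It also missed the threshold with the 100000 best peaks (0.160), at a q of at most 0.01 (0.327) and with the replicate block (0.220). Adjusted over the list alone, 3 members had more regions in PT. The list of gluconeogenesis and fructose metabolism also rose in PT (2.73 ± 0.55 and 3.64 ± 0.80, adjusted p = 0.0264), with 10 of 11 genes positive and none past the threshold over all genes or adjusted over the list alone. This call too was lost with the correlation estimated (adjusted p = 0.613 with an estimated correlation). It was also lost without mTAL replicate 1 (adjusted p = 0.0501), mTAL replicate 2 (0.101), PT replicate 2 (0.158), PT replicate 3 (0.101) or PT replicate 4 (0.0521). In all, 14 of 23 alternatives ended it, among them the 25000 best peaks (0.262), the 100000 best (0.244), all deposited peaks (0.608), a q of at most 0.01 (0.421) and peaks covering at least 50% of a region (0.0981). mTAL replicate 3 had 3.36 regions per gene in this list, above PT replicate 1 (2.55).

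Tight junction genes and transcription factors of the loop and distal nephron went the other way. The tight junction and divalent cation list held 3.42 ± 0.16 regions per gene in mTAL and 2.42 ± 0.43 in PT and fell in PT (camera adjusted p = 0.0264), a call lost with the correlation estimated (adjusted p = 0.539 with an estimated correlation). Of its 16 tested genes, 11 were negative and 3 had more regions in mTAL adjusted over the list alone. The call was lost without mTAL replicate 1 (adjusted p = 0.343), mTAL replicate 2 (0.0750), PT replicate 1 (0.0800) or PT replicate 4 (0.0728). It was also lost with peaks covering at least 50% of a region (0.103), a mean of at least 3 regions (0.0635), the replicate block (0.103), the nearest gene (0.210), gene bodies alone (0.0854), gene ends (0.786), and both doubted libraries left out (0.119). CLDN14, a claudin gene linked to renal calcium handling (gene ID 23562, chromosome 21, 36460621 to 36576569), had 4.67 ± 0.58 regions in mTAL and 1 in every PT library (log2 fold change -1.50, SE 0.07, limma adjusted p = 0.000382) and 3 mTAL-only regions. With all deposited peaks its log2 fold change was 0.26 (adjusted p = 0.703; 0.10 above the median of all genes), with the 100000 best -0.33 (0.434) and at a q of at most 0.01 -0.35 (0.617). Its call was also lost with peaks covering at least 50% of a region (0.0699), the nearest gene (0.174), gene bodies alone (0.144) and the replicate block (0.0807).

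The list of loop and distal transcription factors held 5.79 ± 1.24 regions per gene in mTAL and 3.91 ± 0.59 in PT and fell in PT (camera adjusted p = 0.0264), a call lost with the correlation estimated (adjusted p = 0.605 with an estimated correlation). Of its 24 tested genes, 18 were negative, none passed the threshold over all genes and 3 did adjusted over the list alone, all with more regions in mTAL. The call was lost without mTAL replicate 2 (adjusted p = 0.180), PT replicate 1 (0.0642) or PT replicate 4 (0.150). It was also lost with the 25000 best peaks (0.196), quantile normalization (0.0619), a mean of at least 3 regions (0.0635), the replicate block (0.132), the nearest gene (0.202) and gene ends (0.0538). mTAL replicate 3 had 4.67 regions per gene in this list, below PT replicate 2 (4.75). The number of lists past the threshold was 6, and it was 3 without mTAL replicate 1, PT replicate 1 or PT replicate 4 and 2 without mTAL replicate 2. Some genes are on more than 1 list, so the lists are not independent.

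The other 21 lists did not pass the threshold with the 50000 best peaks. Thick ascending limb salt transport held 4.52 ± 0.33 regions per gene in mTAL and 3.55 ± 0.35 in PT (camera adjusted p = 0.136), and the hormone and enzyme genes of the loop 3.81 ± 0.51 and 2.59 ± 0.38 (adjusted p = 0.137). Salt transport fell in PT with every other number of peaks: the 25000 best (adjusted p = 0.00344), the 100000 best (0.0132), all deposited peaks (0.0138) and a q of at most 0.01 (0.00324). Each was lost with the correlation estimated (adjusted p = 0.254, 0.506, 0.524 and 0.871 with an estimated correlation). The loop hormone and enzyme list passed with all deposited peaks (0.0326; adjusted p = 0.524 with an estimated correlation). The latter list held CYP4F2, an arachidonic acid hydroxylase gene (gene ID 8529, chromosome 19, 15878023 to 15898074), which went against it, with no region in mTAL and 2.50 ± 0.58 in PT (limma adjusted p = 0.00266). That call was lost at a q of at most 0.01 (0.113) and with the replicate block (0.125). Proximal tubule transcription factors gave an adjusted p of 0.164, and passed the threshold without mTAL replicate 3 (adjusted p = 0.0154; adjusted p = 0.553 with an estimated correlation) and with the 25000 best peaks (0.0223; adjusted p = 0.333 with an estimated correlation). Fatty acid oxidation gave 0.164, organic anion and cation transport 0.245 (0.0423 in base pairs covered, adjusted p = 0.691 with an estimated correlation), sodium, phosphate and bicarbonate transport 0.565, apical endocytosis 0.634, and vitamin D, renin-angiotensin and kallikrein genes 0.758. Glucose and amino acid transport gave 0.495. Its member SLC15A2, a peptide transporter gene (gene ID 6565, chromosome 3, 121894401 to 121944188), had 4.67 ± 1.53 regions in mTAL and 1 in every PT library (limma adjusted p = 0.0385). This call was lost without mTAL replicate 1 (adjusted p = 0.154) or 2 (0.0653), or PT replicate 1 (0.0735), 2 (0.0846), 3 (0.101) or 4 (0.0941). It was also lost with the 100000 best peaks (0.0823), all deposited peaks (0.0874), a q of at most 0.01 (0.238), the nearest gene (0.106), gene bodies alone (0.131) and the replicate block (0.262). The 28 tested monogenic blood pressure genes held 4.61 ± 0.28 regions per gene in mTAL and 3.79 ± 0.83 in PT (camera adjusted p = 0.230), with no member past the threshold. This list fell in PT with the 25000 best peaks (adjusted p = 0.00364, 3 members past the threshold), the 100000 best (0.0254, 1 member), a q of at most 0.01 (0.0124, 0 members) and regions given to the nearest gene, a choice made later (0.0399, 0 members). Each was lost with the correlation estimated (adjusted p = 0.333, 0.506, 0.871 and 0.544 with an estimated correlation).

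Markers of other kidney cells did not pass the threshold as lists with the 50000 best peaks. Intercalated cell markers held 2.81 ± 0.13 regions per gene in mTAL and 1.81 ± 0.33 in PT (camera adjusted p = 0.213; with the 25000 best peaks 0.0441, and adjusted p = 0.333 with an estimated correlation), and distal convoluted tubule markers 2.37 ± 0.17 and 1.81 ± 0.23 (adjusted p = 0.306). Endothelial markers held 2.09 ± 0.42 and 2.45 ± 0.23 (adjusted p = 0.213), and stromal and smooth muscle markers 2.78 ± 0.33 and 3.22 ± 0.79 (adjusted p = 0.460). Principal cell markers gave an adjusted p of 0.938, podocyte and parietal cell markers 0.775 and immune markers 0.887. Injury markers held 2.77 ± 0.07 regions per gene in mTAL and 2.27 ± 0.15 in PT (adjusted p = 0.460), with every mTAL library (2.69 to 2.81) above every PT library (2.06 to 2.38). Oxidative phosphorylation (0.890), immediate early (0.758) and housekeeping genes (0.691) did not differ detectably either. Adjusted over the list alone, 1 member had more regions in mTAL in the intercalated cell, immune, organic transport, glucose and amino acid transport, and loop hormone and enzyme lists, and 1 had more in PT in the endothelial and the loop hormone and enzyme lists. In these lists the endothelial transcription factor gene SOX18 (1 region in every mTAL library, 2 in every PT library, limma adjusted p = 1.23e-05) and the myeloid transcription factor gene SPI1 (4.33 ± 0.58 in mTAL, 2 in every PT library, adjusted p = 0.00601) passed the threshold. SOX18 was lost with every other number of peaks (adjusted p = 0.672 to 0.957) and in base pairs covered (0.866). SPI1 was lost with every other number of peaks (0.249 to 0.831), peaks covering at least 50% of a region (0.129), a mean of at least 3 regions (0.0547), gene ends (0.618) and the replicate block (0.175).

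Over all human genes, 54 had more regions in PT and 114 more in mTAL among 15854 tested (limma, adjusted p at most 0.05), in 46 and 108 separate loci, and 2230 genes had an unadjusted p of at most 0.05. Most of these calls rest on small whole numbers. In 104 of the 168 (61.9%) the count was identical in all libraries of each group, and in 98 of them the groups differed by 1 region. The genes with the smallest p were of this kind. ACOT13, CDIPT, CEBPB, CEP55 and CIMIP2C had 1 region in every mTAL library and 2 in every PT library (adjusted p = 1.23e-05). CNOT11 had 3 in mTAL and 1 in PT, and AHR, BANF1, CCDC74A and CEP170 had 2 and 1 (adjusted p = 4.32e-06). The call of CCDC74A was lost without mTAL replicate 2 (adjusted p = 0.677). None of these 10 genes was called with the 25000 best peaks, all deposited peaks (adjusted p = 0.0508 to 0.708), a q of at most 0.01 (0.113 to 0.912), base pairs covered (0.0590 to 0.974) or the nearest gene, and only AHR was called with the 100000 best. With 50% coverage the calls of CDIPT, CEP55, CIMIP2C, AHR, BANF1 and CCDC74A were lost. In 5 kb windows around gene ends only CIMIP2C and CNOT11 of the 10 were called. In gene bodies alone only ACOT13, CNOT11 and CEP170 were called. In base pairs covered CDIPT (-0.02), CEP55 (-0.31) and CIMIP2C (-0.89) were negative, and CCDC74A was positive with all deposited peaks (0.45) and with the nearest gene (0.13). When the spread of a gene was not allowed below the limma trend, a choice made after the data were seen, 41 and 78 calls were left.

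The set of called genes depended on the number of peaks kept. With the 25000 best peaks, 3 of the 54 and 12 of the 114 genes were called again, and with the 100000 best 4 and 10. With all deposited peaks 172 genes had more regions in PT and 58 more in mTAL, with the median of all genes at 0.16, and with peaks at a q of at most 0.01 there were 0 and 2 (2400 genes at an unadjusted p of at most 0.05). Measured as base pairs covered, 32 genes were higher in PT and 248 in mTAL, with the median of all genes at -0.42. The numbers with more regions in PT and in mTAL were 130 and 222 without mTAL replicate 3, 188 and 190 without PT replicate 1, 107 and 184 without PT replicate 2, 97 and 142 without PT replicate 3, and 91 and 176 without PT replicate 4. With both mTAL replicate 3 and PT replicate 1 left out, a choice made later, they were 427 and 424. The excess of calls in mTAL was thus nearly gone without PT replicate 1 alone, and stayed without mTAL replicate 3 alone. Requiring a peak to cover at least 50% of a region gave 24 and 175, with the median of all genes at -0.19.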

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

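The measure used against a wrong label, the median fold for stronger peak calls, the reverse shares of PT-only regions, the comparison of 3 against 3 libraries and the counts over splits were tests chosen only after the result was seen. Of 84 groups of 4 human or rat PT libraries examined for a library far from the others, 7 had one, and chance gives about 1 in 20. In human PT replicate 1, SLC34A1 had 0 regions against 4 in each other PT library, UMOD had 3 against 1, IRX1 had 0 against 1 and PRODH2 had 1 against 2. The share of its kept peaks at gene ends was 22.5%, against 26.5 to 27.1% in the other PT libraries. In human PT replicate 4, SLC5A2 had 4 regions against 3. In human PT replicate 2, CLDN16 had 4 regions against 2. Apart from the share at gene ends, these are gaps of 1 to 4 regions between libraries that otherwise had identical counts.

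Human mTAL replicate 3 held 60.4% of the regions present in all 4 PT libraries and in neither other mTAL library. For mTAL replicates 1 and 2, with the other mTAL libraries left out in the same way, the shares were 10.2% and 13.1%. The PT libraries held 39.6 to 67.5% of the regions of the rest of their own group. That set leaves out every region of mTAL replicate 3, so these shares are not measured alike and cannot be set against its 60.4%. Stronger peak calls stay open: mTAL replicate 2, whose last kept peak had the highest −log10 p, held 13.1%, but by median fold mTAL replicate 3 was the strongest (11.5 against 8.93 and 7.43), and since −log10 p also depends on the unknown read depth, the bound set before on it does not decide. A wrong label as the whole cause is argued against by the regions of mTAL replicates 1 and 2, of which it held 45.3%, against 3.47 to 17.0% in the PT libraries measured in the same way. On the measure set before, over the regions of all 3 mTAL libraries, the highest PT library held 27.9%, which was too high for the bound set then and left the label open. Proximal tubule nuclei in this library, which the dissection would have to have carried over, remain a candidate explanation that meets the test of 60.4% and 45.3%, and a biological difference was not tested.

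More regions were mTAL-only than PT-only in both species. The unequal group sizes cannot be the whole cause, because with 3 libraries of each segment the lowest ratio of mTAL-only to PT-only regions was 2.59 in human and 1.70 in rat. Weaker enrichment of the PT libraries goes with the segment in human by median fold and in rat by the −log10 p of the last kept peak (5.52 to 9.90 in mTAL, 4.65 to 5.23 in PT), and cannot be told apart from a difference between the segments, which the design names and which was not tested separately. Of the mTAL-only regions, 75.6% in human and 60.8% in rat were listed below the 50000 best peaks in at least 1 PT library, between the bounds of 50% and 80% set for that test. In the reverse direction 93.8% of human and 49.0% of rat PT-only regions were listed in at least 1 mTAL library, so being listed is not particular to the weakly enriched libraries in human.

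Among the 54 human genes with more regions in PT, 10 belonged to multi-copy families chosen after the calls were seen, with 7 TAF11L, 2 USP17L and 1 FAM90A genes. In all 4 PT libraries the kept peaks in their windows had a lower median fold (2.50 to 3.35) than all kept peaks of the library (3.58 to 6.60). Repeated sequence that rises above the background of weakly enriched libraries may therefore account for these calls. The full mTAL lists held 18 to 41 peaks in these windows, of which 0 or 1 was among the 50000 best. No biological explanation was tested.

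Whether chance could produce the main counts was examined over the 35 splits of the 7 libraries. For the segment-only regions the real split came first by a wide margin (4856 against at most 1990 in human, 2433 against at most 1060 in rat). Chance is less likely but not excluded for these counts. For the number of human genes called, the real split also came first, but by a small margin, with 168 against 134 and 110 in the next splits. With the spread of a gene not allowed below the trend, it gave 119 against at most 75. First of 35 is the best rank this test can give. The splits were not counted with other numbers of peaks, and only 2 genes were called at a q of at most 0.01. Chance is thus less likely but not excluded for this number. Chance cannot be excluded for the number of human gene lists past the threshold, since 5 of the 35 splits gave at least 6 lists and the highest other gave 9.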

How the results depend on the processing

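Tests chosen only after the result was seen are those that leave out mTAL replicate 3 and PT replicate 1 together, hold a gene's spread at the trend, use another gene window or the nearest gene, set named genes relative to the median of all genes or measure the share at gene ends. The other alternatives given here were chosen before the data were examined, and the scaffold filter on the gene table was not. Over all alternatives, 654 of 807 values of named genes and 93 of 138 values of lists past the threshold kept their direction and their side of the threshold, 107 and 45 were weaker, 11 and 0 were stronger, and 35 and 0 turned direction, counted without correction for a shift of all genes. A named gene that missed the threshold counts as kept when it missed again without turning. Settings in which a gene was not tested are left out. The pooled count of genes therefore does not measure how well the calls held. Human segment-only regions numbered 1990 with the 25000 best peaks, 11405 with the 100000 best, 16207 with all deposited peaks, 13523 at a q of at most 0.01, 6855 with 50% coverage, 13116 with both doubted libraries left out and 5841 to 10964 with 1 library left out. In rat these were 1353, 3675, 6009 and 4478, and 3061 to 9218 with 1 library left out. Human similarity within minus between segments was 0.0742 with the 100000 best peaks, 0.0512 with all peaks, 0.0645 at a q of at most 0.01, 0.118 with both libraries left out and 0.0414 to 0.116 with 1 left out. Fewer libraries cannot reach the threshold there. Rat similarity was 0.0356 at a q of at most 0.01 and 0.00489 to 0.0502 with 1 library left out. Human genes called numbered 2 at a q of at most 0.01, 287 with no filter, 9 with a mean of at least 3 regions, 280 in base pairs covered, 851 with both libraries left out and 190 to 378 with 1 left out. The replicate block gives no weight to PT replicate 4, which has no mTAL partner, so it mixes pairing with the loss of that library. With it there were 143, of which 19 with more regions in PT and 54 with more in mTAL were also called without it, and the tight junction (adjusted p = 0.103) and loop transcription factor lists (0.132) missed the threshold. In human, values of the same replicate number correlated across genes at 0.127, -0.0682 and 0.0614, and others at -0.0803 to 0.115, which gives no sign of pairing by number and does not show whether donors were shared. Rat libraries were not examined for pairing. Lists past the threshold numbered 1 with a mean of at least 3 regions, 1 in windows of 5 kb around gene ends, 3 in gene bodies alone and 2 to 7 with 1 library left out. The cause was not tested for any of these.

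The log2 fold change of named genes changed sign as follows, and the cause was not tested. Some settings move the median of all genes: to 0.16 with all deposited peaks, -0.19 with 50% coverage and -0.42 in base pairs covered, and part of the sign changes are that shift. With the 25000 best peaks EGF was 0.53 and SLC4A4 0.19, and with the 100000 best SLC5A2 was -0.10 and SOX18 -0.0346. With all deposited peaks SLC34A1 was 0.42, SLC4A4 0.0137, CLDN19 0.15, CCDC74A 0.45, CLDN14 0.26 and SPI1 0.39. Relative to that median CLDN19 had no difference left (-0.01), SLC4A4 (-0.15) did not turn, and SOX18 did (-0.02). At a q of at most 0.01 SOX18 was -0.0346. When a peak had to cover at least 50% of a region, SLC5A2 was -0.19, which is 0.00 relative to the median, while SLC34A1 (0.14) and SLC4A4 (0.05) turned relative to it. In base pairs covered SLC5A2 was -0.42, GATM -0.0346, CDIPT -0.0248, CEP55 -0.31, CIMIP2C -0.89 and SOX18 -0.0708. Relative to that median only CIMIP2C (-0.47) among them turned, as did SLC4A4 (0.29). With quantile normalization SLC34A1 was 0.11, and with the replicate block SLC4A4 was 0.0458. With regions given to the nearest gene SLC34A1 was 0.33, SLC5A12 -0.21, CLDN10 0.0530, IRX1 0.88 and CCDC74A 0.13, and in 5 kb windows around gene ends LRP2 was -0.10 and EGF 0.10. With both libraries left out SLC34A1 was 0.74 and SLC4A4 0.21. With 1 library left out LRP2 ranged from -0.0566 to 0.38, SLC34A1 from -0.28 to 0.49, SLC5A2 from -0.0805 to 0.58 and SLC4A4 from -0.30 to 0.16. Not run were windows and nearest genes by gene start, distances to starts, all motif alternatives, all alternatives for rat genes, lists and locations, and those for the comparison of genes between species. Read depth is unknown, so what it limits cannot be given.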

Other observations

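The genes below and the measures on them were chosen only after their values were seen. The transcription factor gene MECOM (gene ID 2122, chromosome 3, 169083507 to 169663712), a member of the list of loop and distal transcription factors, held 7 human mTAL-only regions, more than any other tested gene. It had 18.3 ± 6.66 regions in mTAL (SD, n = 3) and 4.25 ± 1.26 in PT (n = 4), a log2 fold change of -1.84 (SE 0.31) that missed the threshold (limma adjusted p = 0.0839). LIMCH1, OSBPL3 and ARID1B each held 6 mTAL-only regions, and long genes have more room for such regions. OSBPL3, an oxysterol-binding protein gene (gene ID 26031, chromosome 7, 24796537 to 24981845), had 12.3 ± 2.52 and 3.5 ± 0.58 regions (-1.56, adjusted p = 0.0137). INPP4B, a phosphoinositide phosphatase gene, had 9.67 ± 0.58 and 2.50 ± 0.58 (-1.62, adjusted p = 0.00546). LEP, the leptin gene, had 4 regions in every mTAL library and 0.25 ± 0.50 in PT (-2.07, adjusted p = 0.0429). In the intercalated cell list, CLNK had 4 regions in every mTAL library and 0.50 ± 0.58 in PT (-1.82, adjusted p = 0.0908).

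More regions in PT were seen at RPTOR, which encodes a subunit of a growth-regulating kinase complex (gene ID 57521, chromosome 17, 80544838 to 80966368), with 4.33 ± 1.53 regions in mTAL and 16.5 ± 2.38 in PT (1.74, adjusted p = 0.0324) and 3 PT-only regions. DGKG, a diacylglycerol kinase gene, had 2.33 ± 0.58 and 8 ± 1.15 (1.44, adjusted p = 0.0146). PARVB had no region in mTAL and 3.75 ± 1.26 in PT (adjusted p = 0.0169), and UGT3A1, a glycosyltransferase gene, had none and 1.75 ± 0.50 (adjusted p = 0.0201). The melatonin receptor gene MTNR1A had 1 region in every mTAL library and 3.25 ± 0.50 in PT (1.08, adjusted p = 0.00516). DPEP1, a brush border dipeptidase gene on the list of amino acid and small molecule metabolism, had 0.33 ± 0.58 and 4 ± 0.82 (1.97, adjusted p = 0.0644).

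Segment-only regions in the windows of the fixed lists are to be read beside all human regions, with 4184 mTAL-only and 672 PT-only among 124608. Windows of the mTAL core list held 10 mTAL-only regions and 1 PT-only region among 100, and those of the loop and distal transcription factors 16 and 1 among 255. Windows of amino acid and small molecule metabolism held 1 and 5 among 193, and those of gluconeogenesis and fructose metabolism 0 and 2 among 66. The PT core windows held 4 of each among 118, although mTAL-only regions were 6.23 times as frequent overall. Windows of some lists with a positive mean fold change held mTAL-only regions at about the share over all regions. The windows of organic anion and cation transport held 6 and 0 among 165, and those of glucose and amino acid transport 4 and 0 among 137. Those of vitamin D, renin-angiotensin and kallikrein genes held 3 and 0 among 72, and those of proximal tubule transcription factors 3 and 1 among 139. Windows of intercalated cell markers held 8 and 0 among 58. These counts were not tested.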
